A study of Mus musculus with 19 samples.

How the data were processed

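RNA-seq was available for 19 libraries from mouse embryonic stem cells carrying a short hairpin against a control sequence, against 1 of 6 long non-coding RNAs transcribed divergently from a developmental coding gene, or against the coding gene EVX1. Per the labels' protocols, polyadenylated RNA was purified with oligo-dT beads and libraries were made with a stranded mRNA kit. The authors deposited a table of FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library) with 38424 gene or locus entries, of which 11588 were unnamed assembled loci, and 1 column per library. Per the submitters' processing notes, CASAVA and TopHat2 2.0.11 were used and the builds mm10 and mm9 were named. The quantifier, the annotation and whether strand was used in counting are not given in the sources used here. The table holds 116 entries on random chromosomes of the mm9 kind, and only 5.1% of 19220 matched coding symbols had an end within 1000 bp of their GRCm38 position, so positions below are given as mm9 and were not mixed with the GENCODE M21 annotation, which was used only for transcript sequence, GC content and biotype. Starts were changed to 1-based counting.

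Read counts were not used here, so sampling intervals were not computed. Library totals lay between 559050 and 655315 FPKM, and 12255 to 12825 entries reached 1 FPKM in a library. Steps between low loci, taken as whole fragments, gave each library's depth relative to 1 of them as 0.97 to 1.326, a spread of 1.37 times. At 19.2 to 27.8% of the 176 to 367 loci compared, the values lay within 0.02 on the log2 scale of this step. Absolute depth was not derived, and precision is greater for abundant genes.

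Values were analysed as log2(FPKM + 1), a scale that understates the change of low genes. Entries with at least 1 FPKM in at least 2 libraries were kept (14942). One linear model with a mean for each of 12 groups was fitted to all 19 libraries with limma 3.58.1 in R 4.3.3, with a variance prior that follows the mean level. The 7 groups of 2 libraries give 7 residual degrees of freedom, and each of the 5 groups of 1 library is assumed to vary like the others. Each knockdown was compared with its own control by limma's moderated test, two-sided, with Benjamini-Hochberg adjustment at 0.05. The labels do not say whether numbered libraries of a group are separate cultures, separate hairpins or repeats of 1 culture, so p-values measure only the spread between these libraries. The Lhx1os experiment has 1 library per arm and was not tested. There, entries with at least 5 FPKM in 1 of the libraries and a change of at least 2-fold were counted, and the same count between replicates of the groups of 2 served as a yardstick.

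Before the data were examined, 24 gene lists were fixed: core and naive pluripotency, primed epiblast, primitive streak and mesendoderm, definitive endoderm, lateral and cardiac mesoderm, neural progenitor, neuron, glia and neural crest, surface ectoderm and epithelium, extraembryonic endoderm, trophoblast, blood and endothelium, fibroblast and feeder, the Hoxa cluster, the Hoxb, Hoxc and Hoxd clusters, retinoic acid response, the neighbours of the targeted lncRNAs, proliferation, p53 targets, endoplasmic reticulum and integrated stress, interferon response, immediate early genes, hypoxia and glycolysis, and housekeeping. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. For Lhx1os, a list's median was placed among 10000 random lists matched on mean expression. The genes named were fixed by a rule: the target and its neighbour, the 8 largest rises and 8 largest falls among called genes whose knockdown libraries all lay on 1 side of the controls, and up to 4 called members of each list that passed or held at least 3 called genes. For Lhx1os these were the 8 largest rises and 8 largest falls by size and up to 3 members of lists far from the random lists. Entries named as predicted, RIKEN, microRNA, small nucleolar or pseudogene were left out of the ranking. Unnamed assembled loci and entries known only by a sequence accession were left out as well, an extension made after the table was opened. Genes of the fixed lists that passed only when adjusted over the list alone, and markers given only by their level, were named outside this rule, after their values were seen, as were the unnamed loci called in the Evx1as, EVX1 and Sox21os comparisons.

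The test was tried on simulated data with 200 changed genes among the 14942. It recovered 44.4% of 2-fold and 94.6% of 4-fold changes in the Evx1as layout, 44.6% and 94.4% in the EVX1 layout, 74.8% and 96.6% in the Fendrr layout, 68.0% and 98.8% in the Nr2f1as layout, 47.0% and 95.2% in the Sox21os layout, and 68.4% and 97.8% in the Pou3f3os layout. Between 3.7% and 7.4% of the simulated calls were false. The simulated noise had the spread fitted for each gene, the same in every group, as the model assumes. In the data, the SD of the log2 difference between replicates ranged from 0.255 in shEVX1 to 0.464 in shFendrr. The simulated shares therefore do not measure the error rate where groups differ in spread.

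Alternatives set before the data were examined were other pseudocounts and filters, quantile, total and median-ratio scaling, other variance priors, a model of each experiment alone, a replicate block, pooled day-4 controls, and leaving out each library of a group of 2. A correction for GC content, the removal of genes with processed pseudogenes, the removal of 3 abundant unnamed loci, and further alternatives for the list tests were chosen after seeing the data. Transcripts were compared with annotated processed pseudogenes with minimap2 2.31 (at least 95% identity over at least 50% of the length). Among the 99 named genes that could be searched, 4 had such copies, Rps4x, Rps25, S100a11 and Bnip3, and their values are uncertain because reads may be split between copies.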

Results

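The data comprised 19 poly(A) RNA-seq libraries from mouse embryonic stem cells in which divergent lncRNAs, transcribed away from a neighbouring developmental gene, were knocked down during differentiation. The series asked which genes change when such a lncRNA is depleted. In 12 libraries the cells had been differentiated by withdrawal of LIF, the cytokine that maintains the undifferentiated state. These were a control and 2 shEvx1as libraries at day 4, a control and 2 shEVX1 libraries at day 4, 1 control and 1 shLhx1os library at day 6, and 2 control and 2 shFendrr libraries at day 5. The labels give the line CJ7 for the Evx1as experiment and CJ9 for the other 3. The remaining 7 libraries came from 46c cells in N2B27, a serum-free neural medium, with 5 nM retinoic acid for 4 days, and comprised 2 controls, 2 shNr2f1as, 1 shSox21os and 2 shPou3f3os libraries. Library totals lay between 559050 and 655315 FPKM, and absolute depth is not given in the sources used here.

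Lineage markers separated the 2 kinds of culture. Brachyury (T), the primitive streak factor, lay at 143 and 326 FPKM in the day-4 LIF-withdrawal controls, at 114 and 128 FPKM in the day-5 controls and at 20.9 FPKM at day 6, against 1.66 and 0.637 FPKM in the retinoic acid controls. Sox1 and Pax6, factors of the early neural plate, reached 94.1 and 83.7 FPKM and 89.8 and 65.0 FPKM in the retinoic acid controls and stayed at or below 0.986 FPKM in every LIF-withdrawal control. Hand1, a factor of lateral mesoderm and trophoblast, reached 204 FPKM in the day-6 control. The retinoic acid controls differed from each other in pluripotency genes: Pou5f1 (Oct4) was at 43.5 FPKM in replicate 1 and 282 FPKM in replicate 2, and Nanog at 8.65 and 59.1 FPKM.

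The targeted lncRNAs were lower in the knockdown libraries where an entry for them could be named, except for Pou3f3os, but no named entry passed the adjusted test. The Evx1as entry, 5730457N03Rik (chromosome 6, 52258383 to 52264826), was at 0.354 and 0.290 FPKM in shEvx1as against 1.66 FPKM in the control (log2 change -1.01 ± 0.20 SE, adjusted p = 0.728 by limma). In shEVX1, Evx1 itself (chromosome 6, 52263492 to 52268372) was at 30.2 and 37.0 FPKM against 53.9 FPKM (adjusted p = 1). Its log2 change turned to 0.74 when both day-4 controls were taken as 1 group. The control added there, from the Evx1as experiment and labelled as another line, held Evx1 at only 6.71 FPKM. Both shEVX1 libraries lay below their own control. Fendrr (chromosome 8, 123578782 to 123606932) was at 0.358 and 0.0768 FPKM against 1.10 and 1.49 FPKM (log2 change -0.92 ± 0.16, adjusted p = 0.0816). The Lhx1os entry, 1500016L03Rik (chromosome 11, 84339162 to 84349333), was listed at 0 in the knockdown and at 0.0883 FPKM in the control. No entry carried the names Nr2f1as or Sox21os. Beside Nr2f1, the annotated A830082K12Rik (chromosome 13) stayed at or below 0.343 FPKM in the retinoic acid libraries, and the unnamed locus XLOC_006022 (chromosome 13, 78338513 to 78354754) was at 10.2 and 5.98 FPKM in shNr2f1as against 24.7 and 19.3 FPKM, a fall that passed (log2 change -1.37, adjusted p = 0.0323). The entry AK039417, which overlaps one end of Sox21 (chromosome 14), was at 7.77 FPKM in shSox21os against 12.9 and 13.2 FPKM. It was at 11.5 and 8.71 FPKM in shNr2f1as and 8.20 and 13.0 FPKM in the libraries labelled shPou3f3os. The Pou3f3os entry, 2610017I09Rik (chromosome 1, 42705045 to 42751670), was at 2.40 and 4.13 FPKM against 5.20 and 1.98 FPKM, so its values do not separate the libraries labelled shPou3f3os from their controls. Its log2 change of -0.04 turned to 0.25 without shPou3f3os replicate 1, 0.49 without control replicate 1 and 0.01 when libraries were rescaled to the same total. The unnamed locus XLOC_000124 (chromosome 1, 42751588 to 42753888) overlaps one end of 2610017I09Rik. It was at 3.72 and 3.86 FPKM in shPou3f3os, below its controls at 6.76 and 5.68 FPKM. It was also below both controls in shSox21os (2.08 FPKM) and in both shNr2f1as libraries, so the lower level is not particular to shPou3f3os. Evx1 overlaps 5730457N03Rik and Nr2f1 overlaps A830082K12Rik, and their reads cannot be told apart where strand was not used.

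The coding neighbour passed as lower in its own knockdown in 2 of the comparisons, but falls of these genes were not particular to that knockdown. Foxf1, a lateral mesoderm factor (chromosome 8, 123608286 to 123612054), fell from 10.5 ± 0.617 FPKM (SD, n = 2) to 2.82 ± 1.48 FPKM (n = 2) in shFendrr (log2 change -1.65 ± 0.24, adjusted p = 0.0339). Nr2f1, an orphan nuclear receptor of the developing nervous system (chromosome 13, 78328236 to 78338243), fell from 18.9 ± 3.51 FPKM (n = 2) to 7.15 ± 3.12 FPKM (n = 2) in shNr2f1as (log2 change -1.33 ± 0.23, adjusted p = 0.0433). The adjusted p of Foxf1 was 0.976 and that of Nr2f1 0.191 when each experiment was modelled alone, 0.485 and 0.0988 with a pseudocount of 0.1, and 0.0726 and 0.0505 when libraries were rescaled to the same total. Leaving out either control or knockdown replicate 2 also ended both calls, with adjusted p between 0.145 and 0.181 for Foxf1 and between 0.0549 and 0.0977 for Nr2f1. Evx1 was at 5.43 and 1.57 FPKM in shEvx1as against 6.71 FPKM (adjusted p = 1), Sox21 at 19.5 FPKM in shSox21os against 26.3 and 29.0 FPKM (adjusted p = 0.504), and Pou3f3 at 3.57 and 4.18 FPKM in shPou3f3os against 5.86 and 5.38 FPKM (adjusted p = 0.23). Without a test, Lhx1 was at 1.32 FPKM in shLhx1os and 6.06 FPKM in its control. In shEVX1 the lncRNA entry beside Evx1 was at 10.8 and 13.4 FPKM against 10.4 FPKM (adjusted p = 1).

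**Figure D1:**
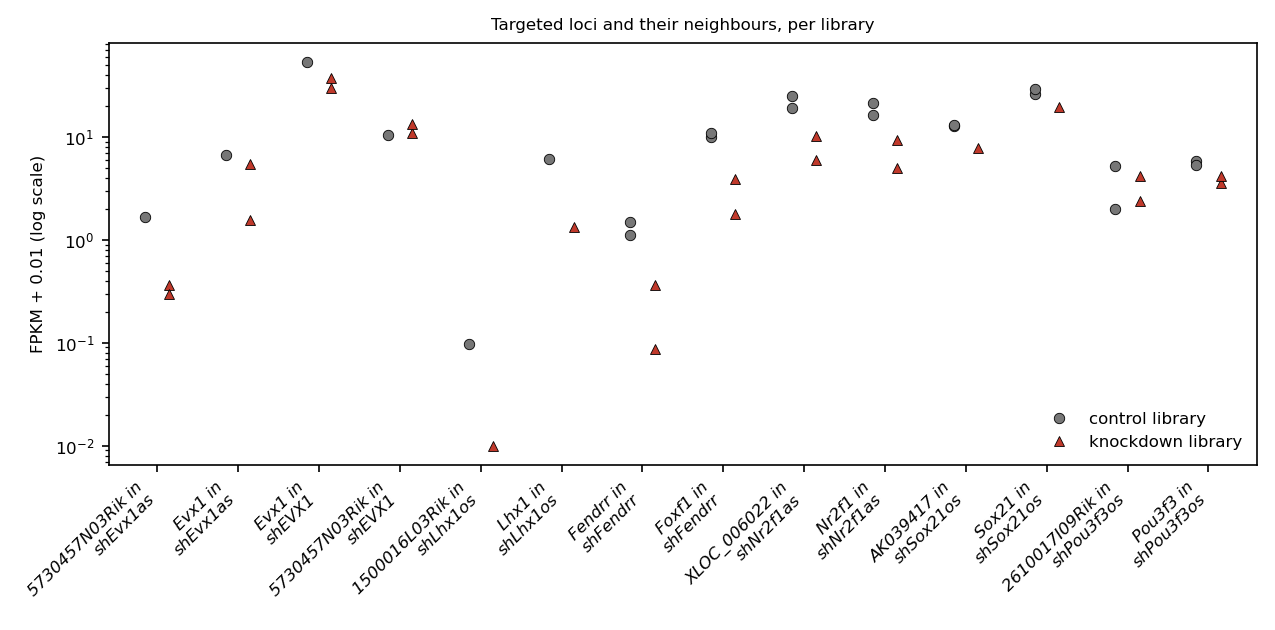
FPKM, with 0.01 added so that a value of 0 can be drawn on the log axis, of each targeted locus and its neighbour in the control libraries (circles) and knockdown libraries (triangles) of its experiment; each point is 1 library. Foxf1 lies at 10.1 and 10.9 FPKM in the controls and at 3.86 and 1.77 FPKM in shFendrr, while 2610017I09Rik overlaps between the groups.

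In shEvx1as, genes of the primitive streak lay lower as a group. Of the 24 measured genes of the primitive streak and mesendoderm list, 23 were lower, with a median log2 change of -0.73. Lhx1, a factor of the anterior streak, was at 5.80 and 0.886 FPKM against 21.3 FPKM, and Mixl1, a mesendoderm factor, at 10.5 and 1.84 FPKM against 19.7 FPKM. Goosecoid (Gsc) was at 10.8 and 1.98 FPKM against 19.3 FPKM, and brachyury at 105 and 25.9 FPKM against 143 FPKM. The definitive endoderm list was also lower, in 10 of 13 genes, with the Nodal and Wnt antagonist Cer1 at 1.47 and 0.327 FPKM against 4.55 FPKM and the endoderm factor Foxa2 at 4.28 and 2.01 FPKM against 11.6 FPKM. The preset list test gave adjusted p = 1.33e-11 for the streak and 3.12e-05 for the endoderm list, and adjusted p = 0.268 for both with an estimated correlation. The streak median was -0.34 without shEvx1as replicate 2 and -0.92 without replicate 1. Adjusted over the list alone, Lhx1 and the Notch ligand Dll3 passed among the streak genes (log2 change -2.64 and -1.34, adjusted p = 0.0499 for each), and Cer1 and Foxa2 among the endoderm genes (adjusted p = 0.0111 and 0.0212).

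Smaller shifts passed the preset test in 4 other lists of the shEvx1as comparison. The interferon response list was lower (median -0.22, adjusted p = 0.000628), as were lateral and cardiac mesoderm (median -0.31, adjusted p = 0.000628) and fibroblast and feeder (median -0.22, adjusted p = 0.019), while p53 targets were higher (median 0.26, adjusted p = 0.019). With an estimated correlation their adjusted p values were 0.561, 0.268, 0.561 and 0.811. Without shEvx1as replicate 2, the adjusted p was 0.297 for interferon response, 0.851 for fibroblast and feeder and 0.125 for p53 targets. Without replicate 1 the medians of interferon response and fibroblast and feeder were -0.39 and -0.38, and without replicate 2 they were -0.04 and 0.10. Over all genes tested, 1 entry was called, the unnamed locus XLOC_010621 (chromosome 17, 83944375 to 83955584), which fell from 3.25 FPKM to 0.0084 and 0.122 FPKM (adjusted p = 0.00171). At an unadjusted limma p under 0.05 there were 654 genes, 416 higher and 238 lower, and no entry was called with a pseudocount of 0.1, with a floor of 5 FPKM or when the day-4 experiments were modelled alone (652, 404 and 1227 genes at an unadjusted p under 0.05). In contrast, 213 were called with no filter beyond a value above 0 and 2 with a variance prior without a trend. The 654 genes are fewer than the share of 0.05 of the 14942 tested that would lie there with no change. Without shEvx1as replicate 1 there were 4 calls and without replicate 2 there were 2.

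In shEVX1, endoderm genes lay higher instead. Cer1 was at 7.16 and 4.03 FPKM against 0.339 FPKM in the control, Foxa2 at 9.50 and 5.76 FPKM against 1.28 FPKM, and the endoderm factor Sox17 at 4.00 and 1.86 FPKM against 0.576 FPKM. These 3 of the 13 definitive endoderm genes passed when adjusted over the list alone (log2 change 2.26, 1.88 and 1.26, adjusted p = 0.000728, 0.00671 and 0.00671), and the list was higher with adjusted p = 0.0146, and adjusted p = 0.503 with an estimated correlation. Of the streak and mesendoderm list, 13 genes were higher and 11 lower, with a median of 0.10 while the test pointed lower (adjusted p = 0.38), and Msgn1, a factor of the presomitic mesoderm, was at 0.507 and 1.49 FPKM against 7.73 FPKM and passed over the list alone (log2 change -2.17, adjusted p = 0.00477).

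Several other lists were lower in shEVX1 by the preset test. Interferon response had a median log2 change of -0.30 (adjusted p = 1.4e-05), surface ectoderm and epithelium -0.33 (adjusted p = 0.000944), trophoblast -0.44, lateral and cardiac mesoderm -0.23 and fibroblast and feeder -0.19 (adjusted p = 0.0213 for each), and core and naive pluripotency -0.22 (adjusted p = 0.0301). With an estimated correlation, adjusted p lay between 0.503 and 0.66 in these 6 lists. All 20 proliferation genes were higher, with a median of 0.15 (adjusted p = 0.033, and 0.66 with an estimated correlation). Leaving out shEVX1 replicate 1 gave adjusted p = 0.145 for lateral and cardiac mesoderm, 0.641 for pluripotency and 0.0747 for proliferation, and leaving out replicate 2 gave 0.0684 for fibroblast and feeder, 0.271 for trophoblast and 0.0619 for proliferation. The pluripotency median was -0.03 without replicate 1 and -0.36 without replicate 2, where that of trophoblast was -0.10. Over all genes 1 entry was called, XLOC_001584 (chromosome 10, 5037276 to 5040848), at 1.64 FPKM in the control and listed at 0 in both knockdown libraries (adjusted p = 0.0429). At an unadjusted limma p under 0.05 there were 496 genes, 334 higher and 162 lower, and no entry was called without shEVX1 replicate 1 or without replicate 2 (289 and 403 genes at an unadjusted p under 0.05). In contrast, 136 were called with no filter beyond a value above 0. The 496 genes are fewer than the share of 0.05 of the 14942 tested that would lie there with no change.

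The effects of the lncRNA and of its coding neighbour were compared directly as a difference of the 2 changes. No gene passed over all genes tested, by limma. At an unadjusted p under 0.05 there were 428 genes, fewer than the share of 0.05 of the 14942 tested that would lie there with no change. After the unnamed locus XLOC_010621 (adjusted p = 0.0606), Cer1 had the smallest adjusted p (difference -3.87 ± 0.50, adjusted p = 0.0729). Adjusted over the list alone, Cer1, Foxa2 and Sox17 differed among the endoderm genes (adjusted p = 0.000127, 0.000981 and 0.00223) and Lhx1 among the streak genes (adjusted p = 0.0479), all lower in the Evx1as effect. Across the 14942 genes, which are not independent replicates, the 2 sets of changes had a Pearson r of 0.055 and a Spearman rho of 0.059. The changes in shEvx1as had r of 0.262 with those in shFendrr and 0.254 with those in shLhx1os, which share no library with them. For shEVX1 these values were -0.035 and -0.123. The Evx1as control held less Evx1 (6.71 FPKM) than the EVX1 control (53.9 FPKM), and each experiment had 1 control library. Cer1, Foxa2 and Sox17 were all higher in the Evx1as control than in the EVX1 control (Sox17 at 2.26 and 0.576 FPKM). Part of their difference between the effects thus lies between the controls. Lhx1 was at 21.3 and 24.3 FPKM in these controls. With no filter beyond a value above 0, 265 genes differed. Leaving out shEvx1as replicate 1 gave 2 differing genes and leaving out replicate 2 gave 3, and r was 0.126 and -0.056 without them.

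**Figure D2:**
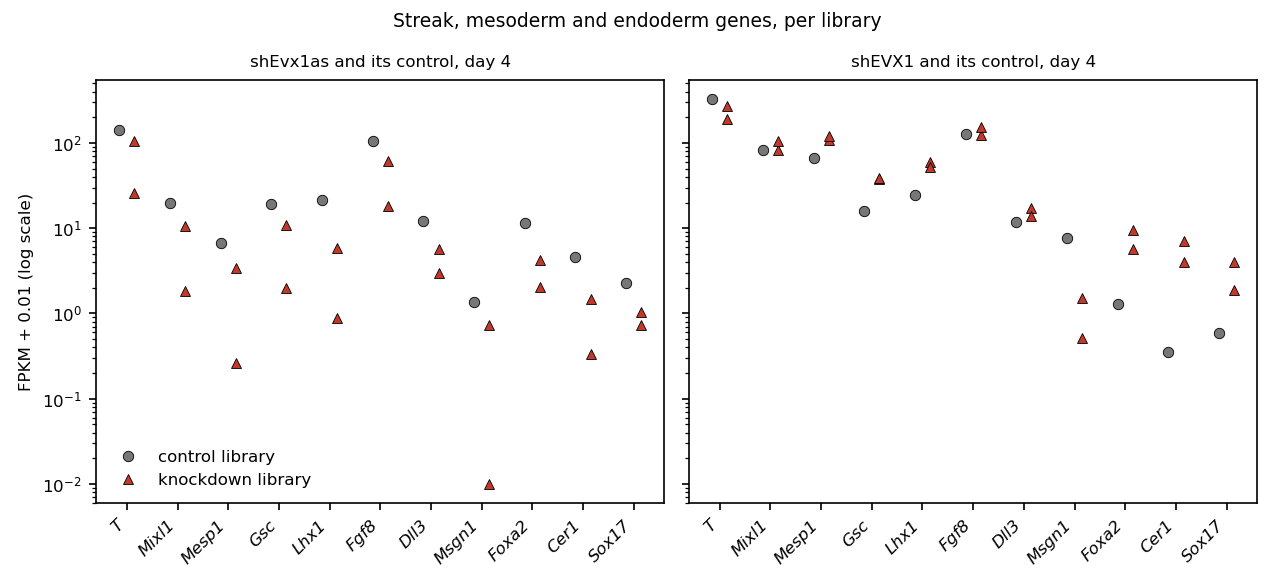
FPKM, with 0.01 added and on a log axis, of 11 genes of the streak, mesendoderm and endoderm lists in the day-4 Evx1as experiment (left) and EVX1 experiment (right); circles are control libraries, triangles knockdown libraries, and each point is 1 library. Cer1 lies at 1.47 and 0.327 FPKM in shEvx1as, below its control at 4.55 FPKM, and at 7.16 and 4.03 FPKM in shEVX1, above its control at 0.339 FPKM.

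The shFendrr libraries held less RNA of lateral and cardiac mesoderm genes. Besides Foxf1, the cardiac T-box factor Tbx20 fell from 8.45 ± 0.0413 FPKM (SD, n = 2) to 2.21 ± 0.429 FPKM (n = 2; log2 change -1.57 ± 0.15, adjusted p = 0.00291), and Hand1 fell from 130 ± 16.6 FPKM to 44.7 ± 14.5 FPKM (log2 change -1.55 ± 0.25, adjusted p = 0.0489). Of the 20 measured genes of this list 17 were lower, with a median log2 change of -0.71 (adjusted p = 1.83e-09, and adjusted p = 0.0732 with an estimated correlation). Adjusted over the list alone 12 fell, among them the VEGF receptor Kdr, Snai2 and Gata4, and cardiac actin (Actc1) rose, from 2.15 and 2.59 FPKM to 8.83 and 7.46 FPKM (adjusted p = 0.0158). Other falls were in Prdm6, a regulator of smooth muscle (log2 change -1.55), the growth factor Fgf3 (-1.52), the endothelial receptor Gpr124 (-1.52), Capn6 (-1.35) and the non-coding RNA Rubie (-1.63), with adjusted p between 0.00291 and 0.0434.

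The neurofilament genes Nefm and Nefl rose in shFendrr, Nefm from 13.5 ± 1.95 to 36.0 ± 3.69 FPKM (SD, n = 2 each, adjusted p = 0.0169) and Nefl from 43.7 ± 3.97 to 103 ± 25.9 FPKM (adjusted p = 0.0415). Nefm overlaps the non-coding entry A230070E04Rik, with which it shares reads where strand was not used. Nefm and Nefl were the 2 called genes of the 16 in the neuron list (adjusted p = 0.0354, and adjusted p = 0.194 with an estimated correlation). Interferon response genes lay lower, in 13 of 14 (median -0.45, adjusted p = 1.92e-07, and 0.194 with an estimated correlation), with Usp18 and Oas1a passing over the list alone. Hypoxia and glycolysis genes were lower in 14 of 17 (median -0.28, adjusted p = 0.000345), and trophoblast genes had a median of -0.25 (adjusted p = 0.0382), with Hand1 and Plac1 passing over the list alone. Their adjusted p was 0.29 and 0.303 with an estimated correlation. Endoplasmic reticulum and integrated stress genes (median 0.26, adjusted p = 8.56e-05), p53 targets (median 0.39, adjusted p = 0.000112) and immediate early genes (median 0.36, adjusted p = 0.000164) lay higher, with the stress factor Atf3 passing over 2 of these lists alone. An estimated correlation gave adjusted p = 0.0964, 0.406 and 0.194 for them.

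In all, 22 genes were called in shFendrr, 8 higher and 14 lower, and 13 with 7 higher and 6 lower when libraries were rescaled to the same total. No gene was called by limma when the Fendrr experiment was modelled alone (532 at an unadjusted p under 0.05). Those 532 are fewer than the share of 0.05 of the 14942 tested that would lie there with no change. Other settings gave other counts: 87 were called with no filter beyond a value above 0, 41 with a pseudocount of 5, 6 with a floor of 5 FPKM and 1 with a pseudocount of 0.1. Leaving out shFendrr replicate 1 gave 231 calls, which included all 22, and leaving out replicate 2 gave 2, both among the 22. Without control replicate 1 there were 4 calls, 2 of them among the 22, and without control replicate 2 there were 9, of which 4 were. The p53 targets were no longer higher without shFendrr replicate 2 (adjusted p = 0.881), where immediate early genes had adjusted p = 0.0591. The neuron list lost its call without either knockdown library (adjusted p = 0.139 and 0.072) or control replicate 2 (0.0882), trophoblast without shFendrr replicate 1 (0.604) or control replicate 2 (0.319), and the stress list without shFendrr replicate 1 (0.0519). Without shFendrr replicate 1 the medians were 0.67 for p53 targets and -0.44 for hypoxia and glycolysis. Without replicate 2 they were -0.18 for hypoxia and glycolysis, -0.28 for interferon response, -0.49 for trophoblast, -0.09 for p53 targets and 0.04 for immediate early genes. Without control replicate 1 the median was -0.16 for hypoxia and glycolysis.

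The shLhx1os library and its day-6 control, 1 library each and therefore without a test, differed in many genes. Of 9015 entries with at least 5 FPKM in 1 of them, 459 were at least 2-fold higher and 562 at least 2-fold lower, 11.3% in all. The same count between replicates of 1 group gave 32 to 393 entries in 7 pairs. The largest differences downward were in the Nodal co-receptor gene Cfc1 (0.808 against 57.5 FPKM), Hand1 (10.5 against 204 FPKM), the carbonic anhydrase Car4 (3.17 against 69.9 FPKM), Prdm6, Rhox6, Ifi27l2a, Hand2 and Gata2. The largest upward were in Stmn4, a regulator of microtubules (36.9 against 0.246 FPKM), the actins Acta1 (1302 against 95.5 FPKM), Acta2 (475 against 34.7 FPKM) and Actg2, calponin (Cnn1), Nefl (63.7 against 5.60 FPKM), Ctgf and Bok.

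Among the lists, 6 had a median difference below all 10000 matched random lists in shLhx1os. These were trophoblast (median -2.68), definitive endoderm (-1.40, with Gata4 and Foxa2), lateral and cardiac mesoderm (-1.19, with Hand1, Hand2 and Foxf1), hypoxia and glycolysis (-1.16, with Ndrg1, Bnip3 and Vegfa), interferon response (-0.96, with Usp18, Bst2 and Oas1a) and proliferation (-0.67, with Ccnb2, Aurkb and Plk1). Blood and endothelium genes (median -0.76) lay at percentile 0.01, the neighbours of the targeted lncRNAs (-0.68) at 0.24, primitive streak and mesendoderm (-0.40, with Cdx2 and Fgf8) at 0.26, and the Hoxb, Hoxc and Hoxd clusters (-0.33) at 0.53. The p53 targets lay above all random lists (median 1.01), with Plk2 at 128 against 24.1 FPKM and Perp at 253 against 60.0 FPKM. Immediate early genes (0.49), surface ectoderm and epithelium (0.36), fibroblast and feeder (0.44, with Tagln and Lox), neural progenitor (0.20, with nestin, Nes, at 55.0 against 6.02 FPKM but Msi1 at 4.06 against 15.5 FPKM) and the stress list (0.17) lay at percentiles 99.99, 99.88, 99.84, 99.41 and 97.53. The other 8 lists lay between percentiles 8.24 (primed epiblast) and 96.92 (neuron). Some genes went against the median of their list. Of the 16 epithelial genes 5 were lower, among them Tfap2c (5.28 against 36.2 FPKM), and of the 15 fibroblast genes 6 were lower. Of the 18 Hoxb, Hoxc and Hoxd genes 4 were higher, among them Hoxb9 (13.8 against 1.36 FPKM) and Hoxc13. Random lists were drawn gene by gene, so these percentiles take no account of list genes that vary together. Nor do they measure the spread between libraries, since each arm had 1 library. The median difference over the entries counted was -0.09. The split of 2-fold changes turned to 610 higher and 462 lower when 3 abundant unnamed loci, which took 7.25% of the total in shLhx1os and 3.94% in its control, were left out and libraries rescaled, and 492 entries changed 2-fold with a pseudocount of 5.

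**Figure D3:**
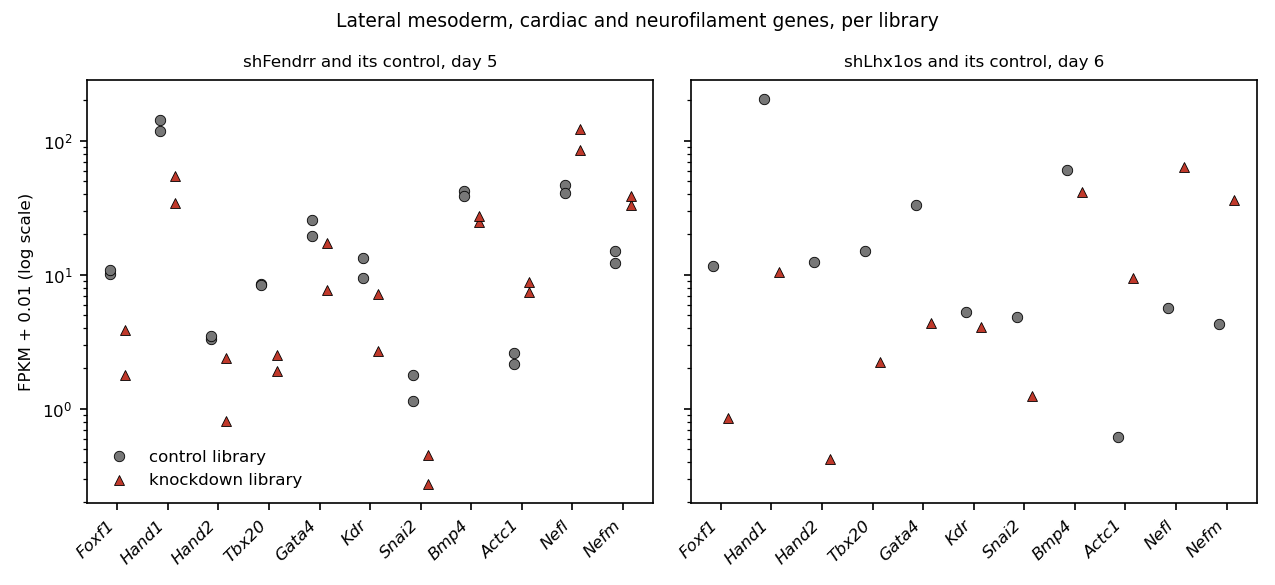
FPKM, with 0.01 added and on a log axis, of lateral mesoderm, cardiac and neurofilament genes in the Fendrr experiment at day 5 (left) and the Lhx1os experiment at day 6 (right); circles are control libraries, triangles knockdown libraries, and each point is 1 library. Hand1 lies at 118 and 142 FPKM in the Fendrr controls against 55.0 and 34.5 FPKM in shFendrr, and at 204 FPKM in the Lhx1os control against 10.5 FPKM in shLhx1os.

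In the retinoic acid cultures, shNr2f1as differed from the controls in single Hox, neural progenitor and epithelial genes, with 1 of 18 Hoxb, Hoxc and Hoxd genes, 3 of 23 neural progenitor genes and 1 of 16 epithelial genes called. These lists had adjusted p = 0.167, 0.295 and 0.343 with an estimated correlation. Hoxb5 fell from 14.2 ± 1.62 FPKM (SD, n = 2) to 2.61 ± 1.91 FPKM (n = 2; log2 change -2.17 ± 0.35, adjusted p = 0.0352), and 15 of the 18 measured Hoxb, Hoxc and Hoxd genes were lower, 10 of them passing when adjusted over the list alone. The hindbrain and spinal cord progenitor factor Dbx1 fell from 15.7 ± 0.300 to 3.58 ± 2.49 FPKM (adjusted p = 0.0463) and Pou3f3, a POU factor of neural progenitors, from 5.62 ± 0.340 to 1.91 ± 0.841 FPKM (adjusted p = 0.0352). The proneural factor Neurog1 fell (log2 change -1.27), as did Myc, Pax2, Hes3, Prdm12, Foxe3 and Serpinf1, with log2 changes between -1.59 and -2.14. The tight junction genes Cldn6 (11.5 ± 5.69 to 42.1 ± 7.91 FPKM, adjusted p = 0.0433) and Cldn3 (log2 change 1.97) rose, together with the microtubule regulator Stmn2 (1.59), the collagen gene Col1a2 (1.41) and the cystine transporter Slc7a11 (1.47), while the stress factor Atf4 fell (-0.75).

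The list tests in shNr2f1as followed these genes. The Hoxb, Hoxc and Hoxd clusters had a median log2 change of -0.71 (adjusted p = 2.8e-08), the Hoxa cluster -0.78 (adjusted p = 0.00158), neural progenitor genes -0.27 with 3 of 23 called (adjusted p = 0.00145), the stress list -0.22 (adjusted p = 0.00145) and retinoic acid response -0.23 (adjusted p = 0.00873). With an estimated correlation these had adjusted p = 0.167 for the Hox and stress lists, 0.295 for neural progenitor and 0.323 for retinoic acid response. Surface ectoderm and epithelium was higher, with a median of 0.76 and 5 of 16 genes passing over the list alone (adjusted p = 0.000642), as was fibroblast and feeder (median 0.33, adjusted p = 0.00438), with 0.343 and 0.323 under an estimated correlation. The neighbours of the targeted lncRNAs (median -0.41, adjusted p = 0.00873), which include Nr2f1 itself, proliferation (-0.07) and p53 targets (-0.25; adjusted p = 0.0465 for both) were lower, and with an estimated correlation adjusted p was 0.323, 0.659 and 0.637. The call was lost without control replicate 1 for surface ectoderm (adjusted p = 0.0614), retinoic acid response (0.129), the neighbours (0.0614), proliferation (0.351) and p53 targets (0.144). Without shNr2f1as replicate 2 it was lost for retinoic acid response (0.248), the neighbours (0.0632), proliferation (0.687) and p53 targets (0.101), and for p53 targets also without replicate 1 (0.0594). The neural progenitor median was -0.10 without shNr2f1as replicate 2 and -0.43 without replicate 1, and that of proliferation was -0.01 and -0.23. Retinoic acid response had -0.03 and the neighbours -0.21 without replicate 2, and retinoic acid response had -0.12 without control replicate 1. Without control replicate 1 the fibroblast median was 0.22, and without control replicate 2 the Hoxa median was -0.48 and that of proliferation -0.18.

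The largest rise in shNr2f1as was in a ribosomal protein gene. Rps4x was at 27.2 and 15.6 FPKM in the controls and rose to 370 and 114 FPKM (log2 change 3.25 ± 0.42, adjusted p = 0.0161), and it and S100a11 have processed pseudogenes near enough in sequence to share reads. The 2 controls stood apart here, since Rps4x lay between 114 and 1234 FPKM in the 17 other libraries of the table. S100a11, the exon junction gene Magoh, Emc2, Clybl and Mgst1 rose with log2 changes between 1.69 and 2.73 (adjusted p between 0.0244 and 0.0496). In all, 101 genes were called, 63 higher and 38 lower, and 72 with 54 higher and 18 lower when libraries were rescaled to the same total. No gene was called by limma when the retinoic acid experiment was modelled alone (2566 at an unadjusted p under 0.05). Other choices changed the count: 331 were called with a replicate block, 169 with a pseudocount of 5, 54 with a variance prior without a trend, 47 with no filter beyond a value above 0 and 42 after quantile normalisation. Leaving out control replicate 1 gave 391 calls, of which 79 were among the 101, and control replicate 2, the library with high Pou5f1, gave 55, of which 20 were among the 101. Leaving out shNr2f1as replicate 1 gave 43 calls, 23 of them shared, and replicate 2 gave 60, 27 of them shared.

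The shSox21os library was compared with the same 2 controls. Myc fell from 30.1 ± 7.16 FPKM (SD, n = 2) to 7.06 FPKM (log2 change -1.93 ± 0.25, adjusted p = 0.0359), and XLOC_006022, the locus beside Nr2f1, fell to 5.57 FPKM (log2 change -1.80, adjusted p = 0.0359). Rps4x, Emc2, the centrosomal gene Haus1, Pramef12 and the thioesterase Acot13 rose, with log2 changes between 1.29 and 3.91 and adjusted p = 0.0359. The lists that shifted were again the Hoxb, Hoxc and Hoxd clusters, with a median of -1.05 and 11 genes passing over the list alone (adjusted p = 5.96e-10), and neural progenitor genes, with a median of -0.48 and Zic1, Pou3f2, Pou3f3, Pax3, Dbx1 and Nr2f1 lower and Fabp7 higher over the list alone (adjusted p = 6.1e-05). Both had adjusted p = 0.183 with an estimated correlation. The Hoxa cluster (-0.45) and the stress list (-0.19) were lower (adjusted p = 0.00824 for both), as were the neighbours of the targeted lncRNAs (-0.46, adjusted p = 0.00188) and p53 targets (-0.20, adjusted p = 0.0399), and fibroblast and feeder (0.33, adjusted p = 0.0364) and surface ectoderm and epithelium (0.40, adjusted p = 0.0433) were higher. An estimated correlation gave adjusted p = 0.183 for the Hoxa, neighbour and stress lists, 0.674 for fibroblast and feeder and 0.768 for surface ectoderm and p53 targets.

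In all, 10 genes were called in shSox21os, 7 higher and 3 lower, 28 with a pseudocount of 5 and 216 with no filter beyond a value above 0. Without control replicate 1 there were 186 calls, which included all 10, and without control replicate 2 there were 29, of which 6 were among the 10. Control replicate 1 was needed for fibroblast and feeder (adjusted p = 0.0959 without it), p53 targets (0.133) and surface ectoderm (0.476), and control replicate 2 for the Hoxa cluster and p53 targets (0.0513 for both).

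In the libraries labelled shPou3f3os 346 genes were called, 239 higher and 107 lower. Hoxb5 fell from 14.2 ± 1.62 FPKM (SD, n = 2) to 2.97 ± 1.66 FPKM (n = 2; log2 change -1.99 ± 0.35, adjusted p = 0.0275), Pax2, a factor of the midbrain and kidney, fell by 1.62 on the log2 scale (adjusted p = 0.0126), and Neurog1 fell by 1.24 (adjusted p = 0.0126). Genes of the integrated stress response fell: Atf4 from 134 ± 1.22 to 72.2 ± 0.632 FPKM (adjusted p = 0.0243), the pseudokinase Trib3 (log2 change -1.29) and Sesn2 (-0.87), while Slc7a11 rose (1.60), and 8 of the 17 genes of this list fell when adjusted over the list alone. Other falls were in Fam25c, Foxe3, Serpinf1, the stress gene Nupr1, Prdm13 and Plk3, with log2 changes between -1.69 and -2.19. The largest rises were again in Rps4x (log2 change 3.72), Rps25 (3.31) and S100a11, which all have such pseudogenes, and in Emc2, Magoh, Rpgrip1, Mgst1 and Tmem216, with adjusted p between 0.0126 and 0.048. Rps25 was at 131 and 20.9 FPKM and Magoh at 9.06 and 2.80 FPKM in these controls, below all 17 other libraries of the table (266 to 1488 and 17.4 to 117 FPKM).

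By list, shPou3f3os was lower in the stress list (median -0.42, adjusted p = 1.54e-05), the Hoxb, Hoxc and Hoxd clusters (-0.44, adjusted p = 5.08e-05), the Hoxa cluster (-0.58, with Hoxa5 called) and p53 targets (-0.27, adjusted p = 0.0169 for both), and the neuron list (-0.28, adjusted p = 0.00642), in which Stmn2 rose. With an estimated correlation adjusted p was 0.104 for the stress list, 0.358 and 0.324 for the Hox lists, 0.692 for p53 targets and 0.181 for neuron. Core and naive pluripotency genes were lower too (median -0.74, adjusted p = 0.00322, and 0.733 with an estimated correlation), with Pou5f1 at 47.2 and 44.6 FPKM against 43.5 and 282 FPKM in the controls. Without control replicate 2 the pluripotency list turned to the other direction (adjusted p = 0.254). Without control replicate 1 its median was -1.54. The p53 call was also lost without control replicate 1 (adjusted p = 0.124) or shPou3f3os replicate 2 (0.0573), where the Hoxa median was -0.37.

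The split of the 346 calls was 323 higher and 72 lower when libraries were rescaled to the same total, 219 and 165 with the median ratio, and 117 and 85 after quantile normalisation. No gene was called by limma when the retinoic acid experiment was modelled alone (2906 at an unadjusted p under 0.05). By other settings, 813 were called with a replicate block and 161 with no filter beyond a value above 0. Leaving out control replicate 1 gave 1240 calls, of which 303 were among the 346, control replicate 2 gave 21, of which 14 were among the 346, shPou3f3os replicate 1 gave 0 (2026 at an unadjusted p under 0.05) and shPou3f3os replicate 2 gave 3. Without control replicate 2 the log2 change was 2.01 for Rps25, 1.21 for Rpgrip1, 1.12 for Tmem216 and -1.09 for Nupr1. Without control replicate 1 it was -1.11 for Prdm13, and none of these passed the test (adjusted p between 0.068 and 0.216).

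The changes in shNr2f1as, shSox21os and the libraries labelled shPou3f3os were correlated. Across the 14942 genes, which are not independent replicates, the changes in shNr2f1as and shPou3f3os had a Pearson r of 0.732, those in shNr2f1as and shSox21os 0.773, and those in shPou3f3os and shSox21os 0.623. Unchanged groups simulated against the same 2 controls gave r of 0.501, 0.409 and 0.409. The simulation gave every library the same spread for a gene. In the data, the log2 difference between replicates had an SD of 0.459 in these controls, 0.363 in shNr2f1as and 0.284 in shPou3f3os. The simulated values may therefore understate what the shared controls alone give. The covariances were 0.109, 0.115 and 0.0973, against simulated 0.0272, 0.0271 and 0.0271. Called in the same direction in shNr2f1as and shPou3f3os were 44 higher and 22 lower genes, against an average of 0 each in simulated unchanged groups with the same controls and 1.01 and 0.27 for independent lists, among them Hoxb5, Neurog1, Pax2, Myc and Atf4 lower and Rps4x, Magoh, Emc2, Slc7a11 and Stmn2 higher. For shNr2f1as and shSox21os 6 higher and 3 lower genes were shared (simulated 0.02 and 0, independent lists 0.03 and 0.01). For shPou3f3os and shSox21os there were 5 and 2 (simulated 0 each, independent 0.11 and 0.02). The simulated groups held no changed gene, so almost no calls, and almost no shared calls, were fixed in advance. The figure for independent lists takes no account of the shared controls. Neither figure therefore shows how many shared calls these controls alone would give. With 1 control for each of shNr2f1as and shPou3f3os, r was 0.124 or 0.495 depending on which had which. How much of the excess over the simulated values comes from the shared controls was not determined.

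**Figure D4:**
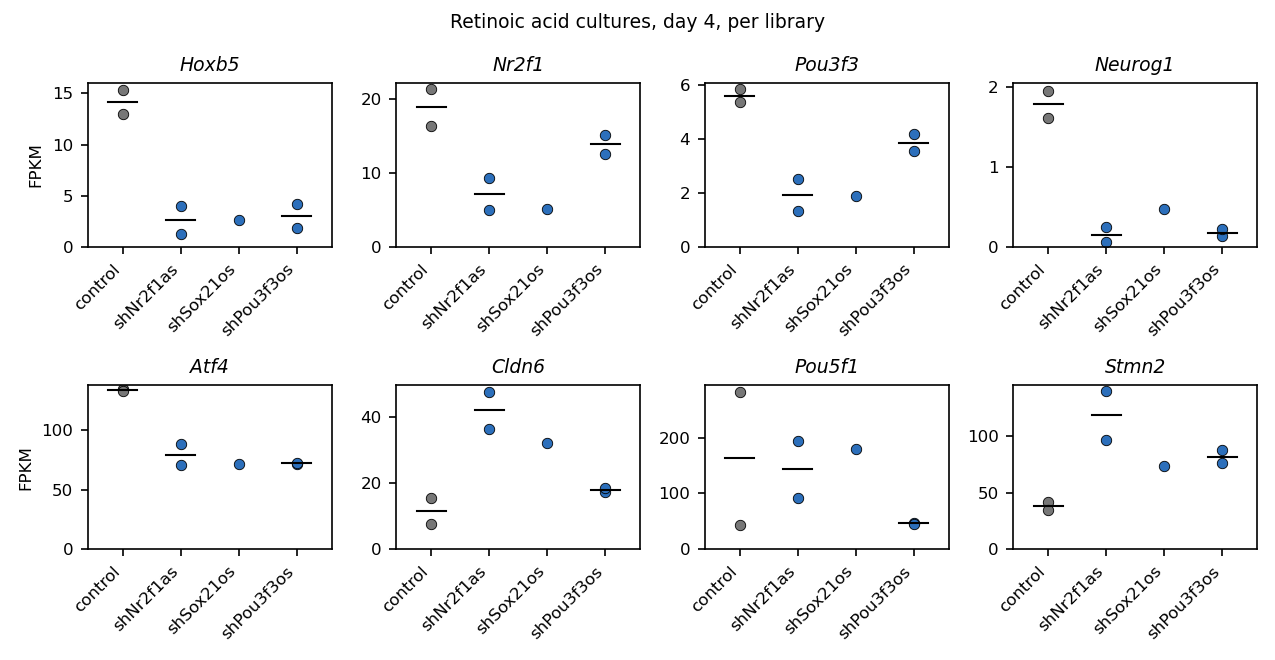
FPKM of 8 genes in the retinoic acid libraries at day 4, with the y axis from 0; each point is 1 library and the bar is the mean of groups with 2 libraries. Hoxb5, Neurog1 and Atf4 lie below both controls in all 5 libraries with a targeting hairpin, and Pou5f1 differs between the controls, at 43.5 and 282 FPKM.

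Several lists passed in none of the 6 tested comparisons. The smallest adjusted p was 0.0706 for blood and endothelium (median 0.19 in shNr2f1as, where the endothelial genes Tek and Sox18 rose), 0.228 for extraembryonic endoderm (median -0.14 in shEVX1), 0.429 for glia and neural crest (0.11 in shNr2f1as), 0.383 for housekeeping genes (0.11 in shSox21os) and 0.0602 for primed epiblast (0.36 in shEVX1). No list call held with an estimated correlation in any of the comparisons. Interferon response had a median below 0 in shEvx1as, shEVX1, shFendrr and shLhx1os alike (-0.22, -0.30, -0.45 and -0.96). So did lateral and cardiac mesoderm (-0.31, -0.23, -0.71 and -1.19). These shifts were therefore not particular to 1 target.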

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

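The tests of explanations in this part were all chosen after the result was seen; the comparison of the Evx1as and EVX1 effects was planned. The tests of control replicate 2 and of undifferentiated cells were changed more than once after their values were seen, and their verdicts changed with them, so values of the earlier tests are given as well. The comparison of Evx1as with EVX1 was singled out because the list test found the effects to differ. The Evx1as effect was lower than the EVX1 effect for definitive endoderm (median difference -0.64, adjusted p = 3.52e-06), primitive streak and mesendoderm (-0.73, adjusted p = 9.43e-05) and primed epiblast (-0.34, adjusted p = 0.035). It was higher for p53 targets (0.31, adjusted p = 0.00375), surface ectoderm and epithelium (0.44, adjusted p = 0.0146), trophoblast (0.66, adjusted p = 0.0219), core and naive pluripotency (0.48, adjusted p = 0.0221) and neuron (0.25, adjusted p = 0.0459). With an estimated correlation the adjusted p of these 8 lists lay between 0.392 and 0.731. The experiments differ in control library and in the cell line given by the labels.

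The 66 genes called alike in shNr2f1as and shPou3f3os form a pattern that several technical differences might give. After a correction for GC content, 51 of the 56 with a GC value still passed in both comparisons, which argues against a GC trend as the whole cause. The correction moved the change in shNr2f1as by more than 0.05 on the log2 scale in 3692 other genes. Such moves were not counted in shPou3f3os. Control replicate 2 alone stays open: 5 of the 66 were still called alike without it and 56 without replicate 1, and 29 of 55 genes called in shNr2f1as against replicate 1 changed the same way in shPou3f3os against replicate 2 (19 of 21 the other way round), while the median change of the 66 against replicate 1 (0.974 and 0.931) decides nothing, since calling kept no gene with under 0.561 of its change there. The test of a share of undifferentiated cells cannot decide, and that cause stays open. Of 23 pluripotency genes, 21 were higher in both shNr2f1as libraries than in both of shPou3f3os (median difference 0.71 to 1.15 by pair). The 66 genes differed by -0.02 to 0.05, but they were chosen for changing alike in both knockdowns. A small difference between the knockdowns was largely fixed by that choice. Against both controls, 20 of the 23 were higher in shNr2f1as and 4 in shPou3f3os (23 and 17 against replicate 1, 4 and 1 against replicate 2). A departure common to both controls stays open, since Rps4x and Magoh were lower in both than in all 17 other libraries, as does a shared effect of the lncRNAs, which was not tested.

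Changes in shLhx1os and shFendrr, which share no control, were correlated across the 14942 genes (Pearson r = 0.551, Spearman rho = 0.559). The correlation was 0.545 after the GC correction, which argues against GC content as the source. It was 0.141 with the change in shFendrr replicate 1 alone and 0.635 with that in replicate 2 alone, in line with replicate 2 carrying most of the likeness. A candidate explanation is a state of the culture common to that library and the shLhx1os library. Whether this comes from the knockdowns or from the cultures was not tested.

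The median log2 change of all genes was 0.05 in both shEvx1as and shEVX1. The unnamed loci XLOC_014354, XLOC_008971 and XLOC_008036 took 8.47% of all FPKM in the Evx1as control and 3.73 and 3.18% in its knockdowns, and 7.35% against 4.19 and 4.21% in the EVX1 experiment. With the 3 loci left out and libraries rescaled the median was -0.008 in shEvx1as and 0.007 in shEVX1, which is consistent with their share setting the small shift. None of the 3 loci passed the adjusted test in these comparisons, and no biological explanation was tested.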

How the results depend on the processing

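Corrections for GC content, the removal of genes with processed pseudogenes and of 3 unnamed loci, and quantile scaling, GC correction and leave-one-out for the lists were chosen after seeing the data. The cause was not tested for any change below. Modelling each experiment alone, with fewer libraries, left 0 calls for Evx1as, EVX1, Fendrr, Nr2f1as and Pou3f3os, with Foxf1 at -1.65 (adjusted p = 0.976) and Nr2f1 at -1.33 (0.191). A pseudocount of 0.1 gave 0, 0 and 1 calls for Evx1as, EVX1 and Fendrr, Foxf1 -1.96 (0.485), Nr2f1 -1.45 (0.0988) and Lhx1 -2.12. A pseudocount of 5 gave 41, 169 and 28 calls for Fendrr, Nr2f1as and Sox21os, 2 genes differing between Evx1as and EVX1, 492 entries changed in shLhx1os and Lhx1 -0.81. With no filter beyond a value above 0, calls were 213 for Evx1as, 136 for EVX1, 87 for Fendrr, 47 for Nr2f1as, 216 for Sox21os and 161 for Pou3f3os, 265 genes differed between Evx1as and EVX1, and Nr2f1 was -1.33 (0.0696). A floor of 5 FPKM gave 0 calls for Evx1as and EVX1, 6 for Fendrr, and Foxf1 -1.65 (0.0553). Quantile normalisation gave 42 calls for Nr2f1as and 202 for Pou3f3os. It gave 1 gene differing between Evx1as and EVX1, and so did the median ratio. Rescaling to the same total gave 0 calls for EVX1, 13 for Fendrr, Foxf1 -1.73 (0.0726) and Nr2f1 -1.36 (0.0505), and turned 2610017I09Rik to 0.009 in shPou3f3os. Without the 3 unnamed loci EVX1 had 0 calls, Foxf1 was -1.76 (0.0672) and 2610017I09Rik 0.006. A prior without a trend gave 2 calls for Evx1as, 54 for Nr2f1as and 3 genes differing, and a robust prior 0 for EVX1. With the day-4 controls as 1 group, Evx1 in shEVX1 turned to 0.74. Evx1 was at 6.71 FPKM in the Evx1as control that joined this group and at 53.9 FPKM in the EVX1 control. The adjusted p over the alternatives other than leave-one-out ranged from 0.00304 to 0.976 for Foxf1 and from 0.0165 to 0.191 for Nr2f1.

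Same-numbered libraries had residual correlations of 0.35 in the Fendrr experiment and 0.303, -0.019 and -0.053 in the retinoic acid experiment. These values do not settle whether the numbers pair the samples. The main model took them as unpaired because the labels do not say what a number marks. The replicate block moved the calls to 331 for Nr2f1as and 813 for Pou3f3os, and gave 30 for Fendrr and 13 for Sox21os, within 1.5 times. The list tests had 46 calls, 0 with an estimated correlation, and 47 and 42 with quantile normalisation and GC correction, which ended 5 and 6 of the 46. The block was not run for Evx1as and EVX1, and in the other comparisons 28 calls held and 4 ended, neuron and trophoblast in shFendrr (adjusted p = 0.0612 and 0.0787) and proliferation and p53 targets in shNr2f1as (0.0554 and 0.0629). With quantile normalisation they were pluripotency in shEVX1 (0.0902), proliferation and p53 targets in shNr2f1as (0.432 and 0.179) and p53 targets in shSox21os (0.127) and shPou3f3os (0.0655). With GC correction they were fibroblast and feeder in shEvx1as (0.0506) and in shEVX1 that list, lateral and cardiac mesoderm and trophoblast (0.0576 each), pluripotency and proliferation (0.0778 each). Counting each called list once for each library left out of its comparison, the call held in 105 cases, was lost in 33 and turned in 2.

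Leaving out 1 library at a time, calls ranged from 2 to 4 for Evx1as, 0 to 0 for EVX1, 2 to 231 for Fendrr, 43 to 391 for Nr2f1as, 29 to 186 for Sox21os and 0 to 1240 for Pou3f3os, and genes differing between Evx1as and EVX1 from 0 to 3. The log2 change ranged from -1.59 to -0.26 for Evx1, 0.05 to 0.34 for 5730457N03Rik in shEVX1, -2.05 to -1.24 for Foxf1, -1.73 to -0.93 for Nr2f1, -0.55 to -0.42 for Sox21 and -0.54 to -0.35 for Pou3f3. The correlation ranged from -0.056 to 0.126 for Evx1as and EVX1, where it turned without shEvx1as replicate 2, from 0.58 to 0.845 for Nr2f1as and Pou3f3os, 0.685 to 0.836 for Nr2f1as and Sox21os and 0.575 to 0.765 for Pou3f3os and Sox21os. Without shPou3f3os replicate 1 and without control replicate 1, 2610017I09Rik turned to 0.254 and 0.486, in a range from -0.571. The p53 list turned in shFendrr without knockdown replicate 2 (adjusted p = 0.881; lowest 6.14e-09) and the pluripotency list in shPou3f3os without control replicate 2 (0.254; lowest 5.28e-13). Each lone library left is assumed to vary like the other groups. Of the values for other named genes, 106 from leave-one-out kept their side of the threshold, 135 lost it, 1 gained it and 2 turned, and under the other alternatives 938 kept it, 223 lost it, 3 gained it, 59 without a test moved and 3 turned. Values near or below 1 FPKM, such as Fendrr and the Lhx1os entry, rest on few fragments.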

Other observations

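The surface ectoderm and epithelium list had a median of 15.1 and 17.8 FPKM in the day-4 controls, 40.1 and 51.6 FPKM at day 5 and 75.8 FPKM at day 6, against 1.99 and 3.73 FPKM in the retinoic acid controls. Trophoblast genes had a median of 21.2 FPKM in the day-6 control and at most 5.01 FPKM in the other 6 controls. Embryonic globin Hbb-bh1 was at 5.95 FPKM in the day-6 control and listed at 0 in shLhx1os. Keratin 8 (Krt8) was at 2187 FPKM in shLhx1os, 1148 FPKM in its control and 8.93 and 17.3 FPKM in the retinoic acid controls. Each day or cell line came with its own experiment, so these levels are given without a comparison.

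Pou5f1 in the retinoic acid libraries was at 92.1 and 194 FPKM in shNr2f1as, 180 FPKM in shSox21os, 47.2 and 44.6 FPKM in shPou3f3os and 43.5 and 282 FPKM in the controls. Dppa5a, another pluripotency gene, was likewise lowest in shPou3f3os and control replicate 1, at 163 and 196, 188, 59.5 and 72.7, and 61.2 and 218 FPKM, while Sox2, which neural progenitors also express, lay between 164 and 196 FPKM in all 7. In the shSox21os library, Nr2f1 was at 5.10 FPKM, Pou3f3 at 1.88 FPKM and XLOC_006022 at 5.57 FPKM, against 7.15, 1.91 and 8.07 FPKM on average in shNr2f1as, so it resembled shNr2f1as in these. The neighbours of the targeted lncRNAs were lower there than in the controls in 5 of 6 genes.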
